A study of Mus musculus with 17 samples.

How the data were processed

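Long noncoding RNA was measured by RNA sequencing in 17 libraries of mouse heart ventricle. Per the labels, total RNA came from the left ventricle (LV) or right ventricle (RV) of male C57Bl/6 mice at postnatal day 0 (P0), 3 (P3) or 7 (P7), and strand-specific paired-end libraries were made from biological replicates. Each group held 3 libraries, except the RV at P7, which held 2. The submitters' processing notes name the aligner STAR 2.4.0j and the genome build mm10. The annotation file, the counting tool and the normalization are not given in the sources used here.

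The authors deposited 1 table per library with a feature ID, a position and a value, and all 17 tables held the same 23940 rows in the same order. Of these rows, 21905 carried a NONCODE transcript ID and 2035 an ID of the kind that transcript assemblers write (TCONS). A total of 170 IDs stood in 2 rows each and 4 in more than 2 rows, with different values, and such rows were kept apart. No position was given for 702 rows. The rows held 20307 distinct positions, and 5055 rows shared their position with another row, so features overlap and can share reads.

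The unit is not named in the tables, and the deposited values were read as FPKM, fragments per kilobase of length and scaled to the depth of the library. The basis was the pattern of low values. Multiplied by the span of the feature, values fell on whole multiples of 0.5 of a step that was constant within a library. Among features with a position and at most 40 such multiples, between 57.2% and 60.2% per library lay within 0.01 of a whole number of them, where the span equals the length used only for features without introns. TPM values would also show steps, so FPKM remains an inference. Under FPKM, the steps correspond to between 13.8 and 20.5 M fragments per library, and this range is the depth behind all values. A value of 1 FPKM over 1 kb then equals 13.8 to 20.5 fragments, so features below 1 FPKM rest on few fragments. Between 34.1% and 49.2% of rows were listed at 0 in a library.

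The positions do not match the build in the submitters' processing notes. On 9 chromosomes they run past the last gene of the GRCm38 (mm10) annotation, GENCODE release M21, on chromosome 7 by 7.08 Mb, and 8 chromosome names end in _random. They are therefore taken to be positions on the older assembly mm9 and are printed as the files give them. No annotation of that build was used here and no position was converted. The tables do not pair the IDs with gene names, and 0 of the IDs matched the RefSeq gene table at hand. Features are therefore identified by position, with few IDs. The mitochondrial chromosome is the exception, because 3 features there have the same start and end as the annotated 12S rRNA gene mt-Rnr1. Gene lists, coding neighbours within 50 kb and the lncRNA at the Ppp1r1b and Tcap locus had been planned and were not analysed here for this reason.

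Differences were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 0.1), with a mean per group over all 17 libraries, a variance trend and robust moderation. Log2 changes are on this scale, which understates the change of low features. Features with at least 0.1 FPKM in at least 2 libraries were kept, without further scaling. Contrasts compared ages within a ventricle, ventricles at each age and over the 3 ages, and the P0 to P7 change between ventricles. An F test asked for any change with age. A feature was called at a two-sided Benjamini-Hochberg adjusted p under 0.05. These settings and the rule for naming features were set before the data were examined.

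The rule took, for each comparison of P7 with P0 and for RV against LV over the ages, up to 10 called features per direction with the largest log2 change. Their mean over all libraries had to be in the upper part (above the median) of the features tested, and the compared groups were not to overlap in any library. For RV against LV over the ages, the differences at the 3 ages had to share their sign instead. The other comparisons took up to 5 per direction by the same rule, and the difference between ventricles up to 5 per direction by smallest p.

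The fits were tested on simulated data with 100 features changed by 1 and 100 by 2 on the log2 scale. The changed features were drawn from those at or above the median level, and all features had the same dispersion. No shift of whole libraries, library set or pairing was simulated, so the results do not cover these or lower features. For LV at P7 against P0, 52% of features changed by 2 on the log2 scale and 6% of those changed by 1 were recovered, and for RV 28% and 2%. For RV against LV over the ages, 96% and 49% were recovered. Called features that had not been changed numbered 8, 0 and 4, in 1 run each. For LV the 8 stood beside 52 and 6 recovered features, a share of calls above the 0.05 aimed at. For LV at P3 against P0, 41% and 3% were recovered, with 3 such calls. For RV against LV at P7, 39% and 5% were recovered, with 5 such calls.

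Alternatives were median scaling, limma without the variance trend, no filter, pseudocounts of 0.01 and 1, each library left out in turn, the replicate number as a block, and only the compared groups in the fit. The block was age and replicate number together for ventricle comparisons, and the replicate number alone for age contrasts. Other alternatives were chosen after seeing the data. They were a filter at 1 FPKM, values summed per position, and a split of the libraries by a mitochondrial feature. In 6 libraries the feature at positions 9203 to 9888 of the mitochondrial chromosome held 132 to 247 FPKM, and in the other 11 it held 7.93 to 25.8 FPKM. These are called the high and the low library set. The labels do not name them. The high set holds LV P0 replicate 3, LV P3 replicates 1 and 3, RV P0 replicate 3 and RV P3 replicates 1 and 3, and none of the P7 libraries. The set was used as a term in the fit, and each set was fitted alone. In the high set alone, RV against LV over the ages is therefore the mean over P0 and P3 only. Tables were handled with Python 3.11.15 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.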

Results

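Noncoding transcripts of the neonatal mouse heart were profiled in the left and the right ventricle at P0, before the ductus arteriosus closes, at P3, a transition stage, and at P7, when most heart muscle cells have matured. The design allows 2 questions, which noncoding features change as the ventricles mature and which differ between the ventricles. Of the 23940 rows, 11079 features passed the filter and were tested. The depth implied by the values averaged 18.1 M fragments in LV P0, 18.5 M in LV P3, 17.5 M in LV P7, 17.5 M in RV P0, 16.6 M in RV P3 and 18.4 M in RV P7. On principal components of the tested features, the first 3 components held 25.9%, 9.02% and 7.97% of the variance. RV P3 replicate 2 stood apart on the third component, at 57.7 against -16.2 to 10.9 for all others. It also had the lowest depth, 13.8 M fragments, and the most rows at 0, 49.2%. The 2 RV P7 libraries lay at 44.7 and 24.2 on the first component. All positions are those of the files, taken to be mm9, and the genes at these positions were not analysed here.

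From P0 to P7, the left ventricle lost several features that were abundant at birth and gained others that had been close to 0. The feature TCONS_00049214 on chromosome 6, positions 87387308 to 87387671, measured 27.4 ± 9.30 FPKM at P0 (SD, n = 3) and 0.810 ± 0.246 at P3 (SD, n = 3), and was listed at 0 in all 3 libraries of P7. Feature NONMMUT020952 on chromosome 14, positions 55590746 to 55591524, fell from 36.1 ± 4.72 to 0.218 ± 0.0673 FPKM (SD, n = 3 each; log2 change -6.84 ± 0.51 SE, limma adjusted p = 5.76e-08). In the other direction, NONMMUT049230 on chromosome 4, positions 119963955 to 119976497, rose from 0.00394 ± 0.00683 to 2.22 ± 0.532 FPKM (SD, n = 3 each; log2 change 4.46 ± 0.30 SE, limma adjusted p = 1.05e-08). Another, on chromosome 7, positions 140939248 to 140945536, rose from 0.863 ± 0.305 to 16.8 ± 6.33 FPKM (SD, n = 3 each; limma adjusted p = 3.61e-06). On chromosome 3, the feature at positions 63285069 to 63287868 was listed at 0 in the 3 libraries of P0 and reached 3.46 ± 1.16 FPKM at P7 (SD, n = 3).

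On chromosome 14, 4 features named by the rule in both ventricles lay within 23.1 kb, at positions 55590746 to 55613820. This stretch was drawn around them after their values were seen. In the left ventricle 3 of them fell and 1 rose. Besides NONMMUT020952, the feature at 55600011 to 55600850 fell from 4.46 ± 0.140 to 0.0337 ± 0.0328 FPKM (SD, n = 3 each; limma adjusted p = 4.00e-08). The feature at 55613573 to 55613820 measured 1.77 ± 0.159 FPKM at P0 (SD, n = 3) and was listed at 0 in all P7 libraries of both ventricles. The rising feature, NONMMUT020955 at 55597685 to 55610438, spans the falling one at 55600011. It rose from 0.154 ± 0.0999 to 3.37 ± 0.0325 FPKM in the left ventricle (SD, n = 3 each; log2 change 3.87 ± 0.44 SE, limma adjusted p = 1.01e-05). In the right ventricle it rose from 0.209 ± 0.220 (SD, n = 3) to 4.74 ± 1.46 FPKM (SD, n = 2; log2 change 4.20 ± 0.49 SE, limma adjusted p = 3.67e-05). The files give no strand, so features that overlap may share reads.

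**Figure D1:**
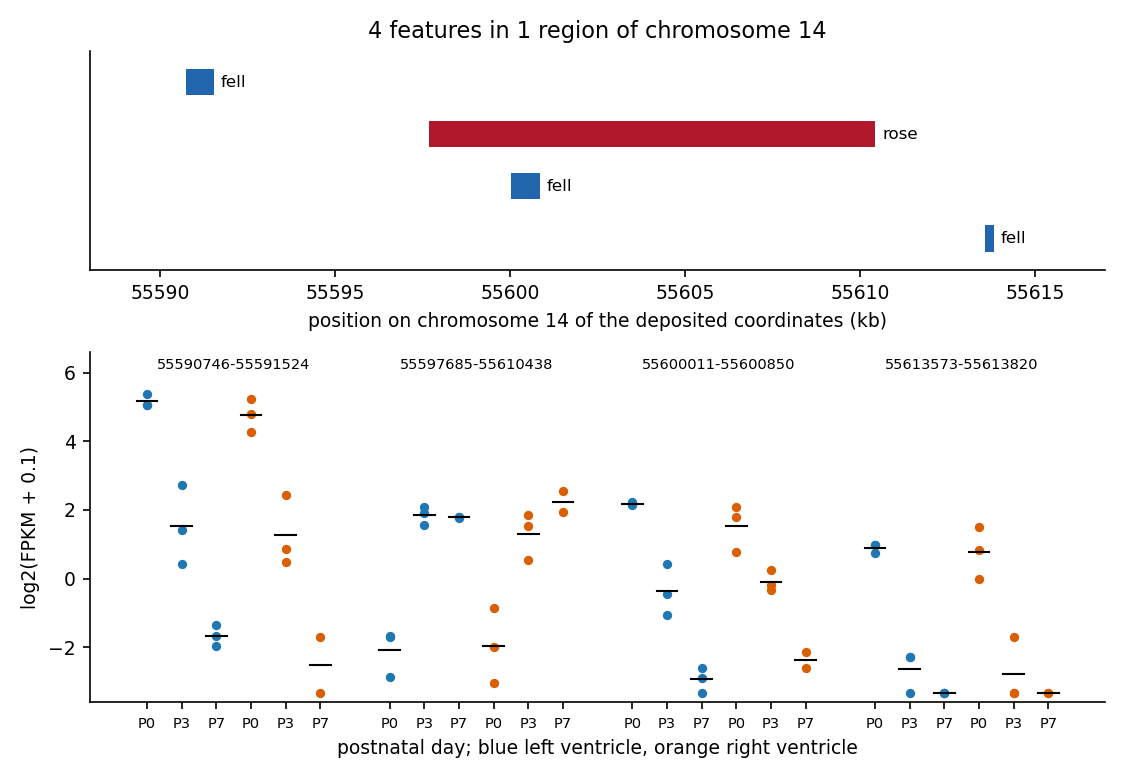
The upper panel maps the 4 features of chromosome 14 to scale, in kb, with the direction from P0 to P7 written beside each (red rose, blue fell), and the lower panel gives log2(FPKM + 0.1) of each library as a point, blue for the left and orange for the right ventricle, with a line at the group mean. The feature from 55597685 to 55610438 is low at P0 and high at P3 and P7, and the other 3 run the opposite way.

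Across the left ventricle, 1245 of 11079 features were called between P7 and P0 by limma, 288 higher and 957 lower at P7. Of these, 250 rose and 766 fell by more than 1 on the log2 scale. The median of all tested features was itself lower at P7, by a log2 change of -0.32. After median scaling, which removes this shift, 509 features were higher and 399 lower, and 687 of the calls, 288 higher and 399 lower, were shared between both scalings. The count was 782 without LV P0 replicate 1, 666 without LV P0 replicate 3, 776 without LV P7 replicate 1 and 738 without a filter. In the low library set alone, 183 features were higher and 453 lower, and with the set as a term 278 and 752.

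**Figure D2:**
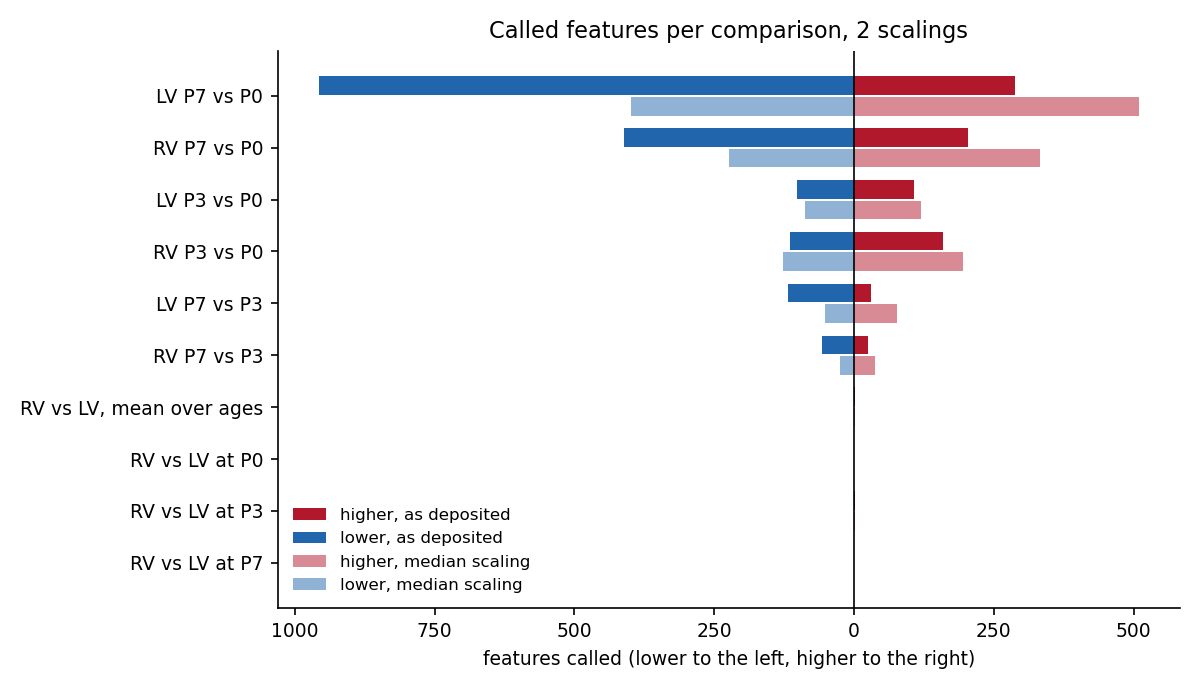
Bars give the number of features called per comparison, higher to the right and lower to the left, on the values as deposited (dark) and after median scaling (light). In the left ventricle at P7 against P0 the split is 288 higher and 957 lower as deposited, and 509 higher and 399 lower after scaling, while comparisons of the ventricles hold at most 2 calls.

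Of the 10 features named per direction, the right ventricle shared 7 of the rising and 6 of the falling ones with the left. TCONS_00049214 measured 27.1 ± 9.60 FPKM at P0 (SD, n = 3), 3.19 ± 0.807 at P3 (SD, n = 3) and 0.0736 ± 0.104 at P7 (SD, n = 2; log2 change -7.37 ± 0.39 SE, limma adjusted p = 1.01e-09). NONMMUT020952 fell from 28.0 ± 9.06 (SD, n = 3) to 0.103 ± 0.146 FPKM (SD, n = 2; limma adjusted p = 1.84e-07). NONMMUT049230 rose from 0.0174 ± 0.0302 (SD, n = 3) to 2.17 ± 0.351 FPKM (SD, n = 2; limma adjusted p = 1.76e-07). The chromosome 7 feature at 140939248 rose from 1.72 ± 0.880 (SD, n = 3) to 9.21 ± 6.48 FPKM (SD, n = 2; limma adjusted p = 0.00761), and without RV P7 replicate 2 its adjusted p was 0.146. This feature lies outside the naming rule for the right ventricle and is given for comparison with the left. A feature on chromosome 13, positions 53111296 to 53113855, rose from 0.0825 ± 0.0910 (SD, n = 3) to 2.61 ± 0.172 FPKM (SD, n = 2; limma adjusted p = 8.07e-05). In the left ventricle it rose from 0.0292 ± 0.0506 to 2.62 ± 0.457 FPKM (SD, n = 3 each; limma adjusted p = 3.40e-06).

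In all, 615 features were called in the right ventricle by limma, 203 higher and 412 lower at P7, with a median log2 change of -0.27 over all features. Median scaling gave 332 higher and 224 lower. The P7 group held 2 libraries, and a fit without either leaves 1, which is assumed to vary like the other groups. Without RV P7 replicate 1, 90 features were higher and 90 lower, with a median log2 change of -0.16, and without RV P7 replicate 2, 97 were higher and 310 lower, with a median of -0.40. The count was 394 without RV P0 replicate 1 and 408 without RV P0 replicate 3. It was 380 without a filter, 382 with only the RV groups of P0 and P7 in the fit, and 370 in the low library set alone, where 138 features were higher and 232 lower.

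**Figure D3:**
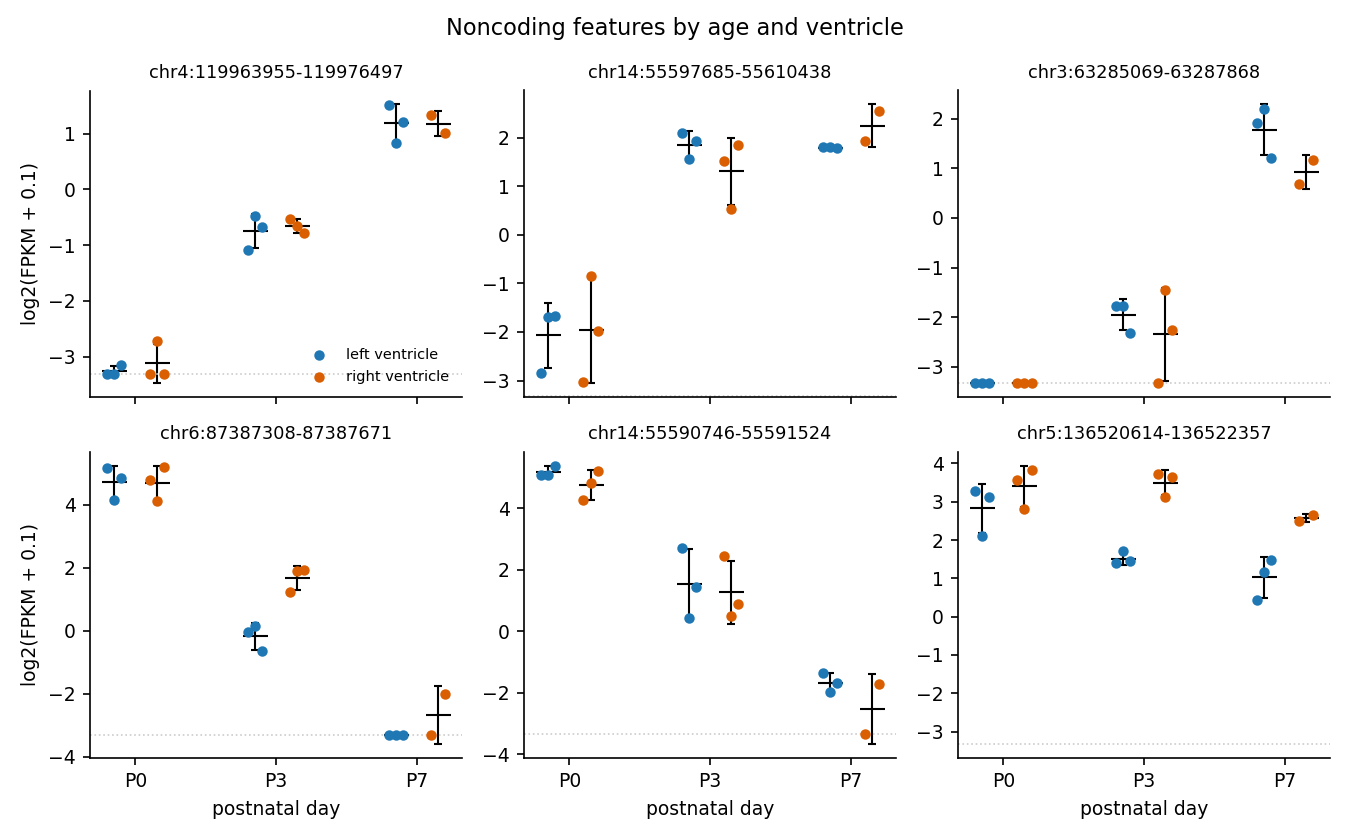
Points give log2(FPKM + 0.1) of single libraries at P0, P3 and P7 for 6 features, blue for the left and orange for the right ventricle, with black marks for group means with SD and a dotted line at 0 FPKM. The upper 3 features rise and the first 2 of the lower row fall in both ventricles, and the feature on chromosome 5 is higher in the right ventricle.

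The changes from P0 to P7 in the left and the right ventricle ran together. Of 1434 features called in either ventricle, 1369 (95.5%) changed in the same direction in both. A total of 145 features were called higher and 281 lower in both ventricles, against 5.28 and 35.6 for independent lists of these lengths, and none was called in opposite directions. Both lists come from the same fit with a shared variance per feature, so they are not independent and this is no test of chance. Over all tested features, 70.3% in the left and 68.7% in the right ventricle changed below 0, which raises the share of equal signs. Across all tested features, which are not independent replicates, the log2 changes of the ventricles had Pearson's r = 0.63. The P0 and P7 libraries of the 2 ventricles are distinct, but the labels do not say whether they share animals. The test of the difference between ventricles in the P0 to P7 change called 0 features with limma, and 454 had an unadjusted p under 0.05 where 554 are expected by chance. The smallest adjusted p was 0.339, for a feature without a position that fell from 47.7 ± 9.03 to 1.86 ± 0.355 FPKM in the left ventricle (SD, n = 3 each). In the right ventricle it fell from 27.5 ± 6.50 (SD, n = 3) to 3.72 ± 1.25 FPKM (SD, n = 2). The difference test called 1 feature without a filter on low values.

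**Figure D4:**
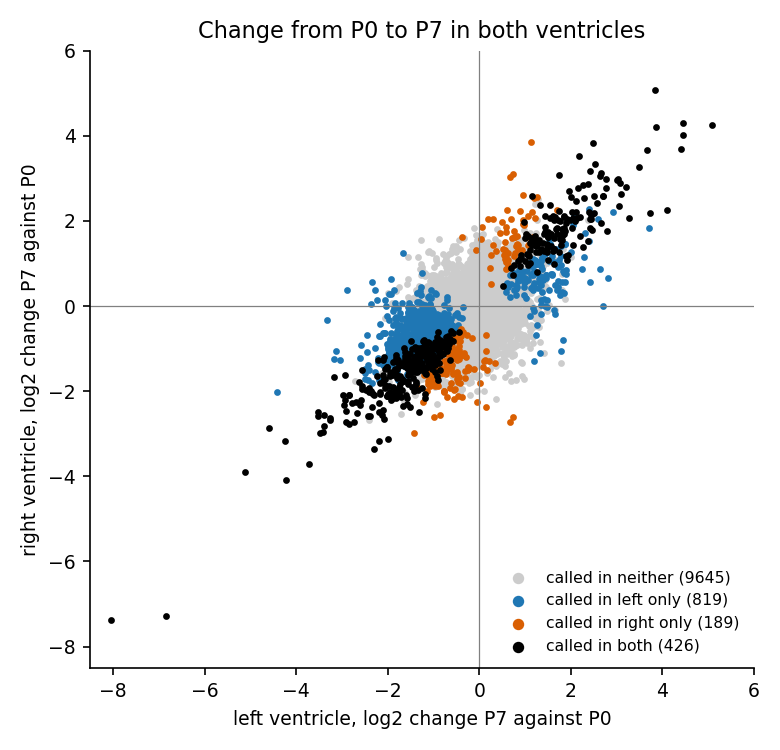
Each point is 1 of the 11079 tested features, with the log2 change from P0 to P7 of the left ventricle on the x axis and of the right ventricle on the y axis. The 426 features called in both ventricles are black, those called in the left or the right alone blue and orange and those called in neither grey, and the black points lie in the lower left and upper right quadrants.

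Several of these changes were in place by P3. In the left ventricle NONMMUT020955 rose from P0 to 3.57 ± 0.668 FPKM at P3 (SD, n = 3; limma adjusted p = 4.29e-05). A feature on chromosome 9, positions 95464523 to 95468440, rose from 0.531 ± 0.136 to 6.68 ± 0.823 FPKM by P3 and measured 6.90 ± 1.09 FPKM at P7 (SD, n = 3 each; log2 change P3 against P0 3.44 ± 0.23 SE, limma adjusted p = 2.52e-08). In the right ventricle it measured 0.725 ± 0.225 FPKM at P0 and 6.56 ± 1.05 at P3 (SD, n = 3 each), and 7.71 ± 1.33 at P7 (SD, n = 2). On chromosome 19, a pair of neighbouring features at 9683167 to 9683812 and 9684828 to 9699306 rose in the right ventricle. The first went from 0.0310 ± 0.0536 to 1.10 ± 0.325 FPKM (SD, n = 3 each; limma adjusted p = 0.000132), and the second was listed at 0 at P0 and measured 0.962 ± 0.681 FPKM at P3 (SD, n = 3; limma adjusted p = 0.000604). With the library set as a term their adjusted p values were 0.000186 and 0.000895. Each set alone left 1 library at P3 or at P0, so only effect sizes are given. The first had log2 changes of 2.58 (low set) and 3.78 (high set), and the second 4.21 (low set) and 2.74 (high set). Both were also higher at P3 in the left ventricle. There the libraries held 0 to 0.102 FPKM of the first at P0 and 0.951 to 1.47 at P3. The second measured 0 to 0.0877 FPKM at P0 and 0.317 to 1.12 at P3 in these libraries. On chromosome 12, the feature at 100140406 to 100143271 fell in the right ventricle from 1.56 ± 0.265 to 0.0800 ± 0.0656 FPKM (SD, n = 3 each; limma adjusted p = 5.60e-06). It was also lower at P3 in the left ventricle, with 1.77 to 2.28 FPKM per library at P0 and 0.368 to 0.714 at P3.

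Between P3 and P0, limma called 209 features in the left ventricle, 107 higher and 102 lower, and 273 in the right, 159 higher and 114 lower. The left count was 114 without LV P0 replicate 1, 134 without LV P0 replicate 3, 136 without LV P3 replicate 3 and 131 without a filter, and the right count 172 with only the compared groups in the fit. Within the low and the high library set, limma called 28 and 48 features in the left ventricle and 72 and 47 in the right, from at most 2 libraries per group. With the set as a term the split was 110 higher and 146 lower in the left ventricle and 163 and 176 in the right.

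Between P7 and P3 limma called 148 features in the left ventricle (30 higher, 118 lower) and 82 in the right (25 higher, 57 lower). A feature on chromosome 17, positions 32044822 to 32046318, rose in the left ventricle from 0.0240 ± 0.0416 to 2.06 ± 0.416 FPKM (SD, n = 3 each; log2 change 4.15 ± 0.36 SE, limma adjusted p = 3.50e-06). In the right ventricle it rose from 0.0517 ± 0.0895 (SD, n = 3) to 1.19 ± 0.0768 FPKM (SD, n = 2; limma adjusted p = 0.000661). The chromosome 3 feature at 63285069 rose from 0.162 ± 0.0527 to 3.46 ± 1.16 FPKM in the left ventricle (SD, n = 3 each; limma adjusted p = 6.70e-05). TCONS_00049214 continued to fall from P3 to P7 in both ventricles, with limma adjusted p = 7.22e-05 in the left and 9.46e-06 in the right, and with a pseudocount of 1 the left value was 0.113.

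These P7 against P3 counts depended on the libraries. All P7 libraries belong to the low set and only 1 P3 library per ventricle does. A fit within that set takes the spread of P3 from the other groups. Its smaller counts therefore cannot decide whether the changes depended on the set. With the set as a term the counts were 51 and 39, against 148 and 82 without it. Median scaling gave 76 higher and 52 lower in the left ventricle and 38 and 25 in the right. Leaving out a P3 library of the high set (replicate 1 or 3) lowered the count in both ventricles. Leaving out the low-set P3 replicate 2 raised it in the left ventricle and lowered it in the right. The left count was 18 without LV P3 replicate 1, 201 without LV P3 replicate 2, 37 without LV P3 replicate 3, 95, 56 and 52 without LV P7 replicates 1, 2 and 3, 53 without a filter, 74 without the variance trend and 77 with only the compared groups. The right count was 43, 38 and 49 without RV P3 replicates 1, 2 and 3, 12 without RV P7 replicate 1, 47 without the variance trend and 40 with only the compared groups.

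Testing all 4 age contrasts of the ventricles together, the F test of limma called 1173 features with any change with age. The count was 745 without a filter and 591 in the low library set alone.

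Few features were called between the ventricles themselves in the main fit, which pairs no libraries. More were called over the ages with age and replicate number as a block, as given under the processing below. Over the 3 ages, 1 of 11079 features was called, NONMMUT054852 on chromosome 5, positions 136520614 to 136522357, with a log2 difference of 1.36 ± 0.19 (RV minus LV, SE; limma adjusted p = 0.00656). It measured 11.0 ± 3.73 FPKM in RV against 7.47 ± 2.89 in LV at P0 and 11.3 ± 2.4 against 2.77 ± 0.337 at P3 (SD, n = 3 each). At P7 it measured 5.87 ± 0.407 FPKM in RV (SD, n = 2) and 2.03 ± 0.725 in LV (SD, n = 3), so the RV mean was higher at 3 of 3 ages. An unadjusted p under 0.05 was found for 765 features, where 554 are expected by chance. In the low library set alone the log2 difference of NONMMUT054852 was 1.15. The high set holds no P7 library, so the difference there is the mean over P0 and P3 only, and it was 1.49. No feature was called over the ages in the low set, without the variance trend or without RV P7 replicate 2. The count was 2 without LV P7 replicate 2, 2 without LV P7 replicate 3, 3 without RV P3 replicate 1, 2 in the high set and 2 with values summed per position.

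At single ages, limma called 0 features between the ventricles at P0, 1 at P3 and 1 at P7, with 587, 651 and 495 at an unadjusted p under 0.05. More were called at P3 and at P7 with age and replicate number as a block, as given under the processing below. At P0 the count was 1 without LV P0 replicate 3 and 2 without RV P0 replicate 2. Without a filter it was 1 at P0, 0 at P3 and 15 at P7, of which 13 were higher and 2 lower in RV. At P3 the feature was again NONMMUT054852 (log2 difference 1.98 ± 0.31 SE, adjusted p = 0.0441), and its adjusted p passed 0.05 under 12 of 28 alternatives. It was 0.405 without RV P3 replicate 3, and 0.677 (log2 difference 1.41) in the low set, which holds 1 library per ventricle at P3. The P3 count was 0 without LV P0 replicate 3, LV P3 replicates 1, 2 or 3, LV P7 replicate 2, RV P0 replicate 1 or RV P3 replicates 2 or 3, and 3 without RV P3 replicate 1, RV P7 replicate 1 or RV P7 replicate 2. At P7 it was a feature on chromosome 16, positions 24097633 to 24098149, which measured 0.581 ± 0.252 FPKM in LV (SD, n = 3) and was listed at 0 in both RV libraries (limma adjusted p = 0.0155). This feature lies below the median level, falls outside the naming rule and was chosen after its values were seen. Its log2 difference was -2.70 ± 0.39 (RV minus LV, SE), and its call was lost under 8 of 26 alternatives. Without LV P7 replicates 1 and 3 the log2 differences were -2.71 and -2.43, with adjusted p values of 0.104 and 0.166. Without RV P7 replicate 1 or 2 the log2 difference was -2.70. There the 1 RV library left was still listed at 0 and is assumed to vary like the other groups. The adjusted p was 0.189 with a pseudocount of 0.01, 0.298 with the replicate block, 0.308 with only the compared groups and 0.102 in the low library set.

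On the mitochondrial chromosome, whose annotated 12S rRNA bounds match deposited features, 1 feature at each ribosomal RNA gene held a high value. Both were chosen after their values were seen, and the other 3 features at the same positions averaged 3.56, 0.0170 and 0.0449 FPKM over all libraries. The most abundant feature at 70 to 1024, the span of mt-Rnr1 (12S rRNA), rose in the left ventricle from 1037 ± 216 FPKM at P0 to 2205 ± 621 at P7 (SD, n = 3 each; log2 change 1.07 ± 0.30 SE, limma adjusted p = 0.0358), and the adjusted p was 0.122 without LV P0 replicate 1, 0.123 without LV P0 replicate 3, 0.0896 without LV P7 replicate 1, 0.109 without LV P7 replicate 2 and 0.0517 without the variance trend. In the right ventricle it measured 1246 ± 434 (SD, n = 3) and 1808 ± 107 FPKM (SD, n = 2; limma adjusted p = 0.350). Another feature at the same positions measured 3.17 ± 0.472 FPKM at P0 and 3.03 ± 0.764 at P7 in the left ventricle (SD, n = 3 each; limma adjusted p = 0.869). The most abundant feature at 1094 to 3703 starts where mt-Rnr2 (16S rRNA) starts, runs past the end of that gene at 2675 and also overlaps mt-Tl1 and the protein-coding mt-Nd1. It rose from 15091 ± 963 to 21708 ± 1106 FPKM in the left ventricle (SD, n = 3 each; log2 change 0.53 ± 0.11 SE, limma adjusted p = 0.00454). In the right it rose from 15209 ± 1364 (SD, n = 3) to 21108 ± 1662 FPKM (SD, n = 2; log2 change 0.47 ± 0.12 SE, limma adjusted p = 0.0281). Without the variance trend these adjusted p values were 0.160 and 0.344, and after median scaling the right value was 0.0947. The right value was also 0.0774 without a filter, 0.103 with a pseudocount of 1, 0.0527 without LV P0 replicate 3, 0.109 and 0.0877 without RV P0 replicates 1 and 3, and 0.305 and 0.0604 without RV P7 replicates 1 and 2. Within the low library set the log2 changes of this feature were 0.52 and 0.44, with adjusted p = 0.00214 and 0.0163.

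The libraries of P0 and P3 fell into sets that the labels do not name. The feature at mitochondrial positions 9203 to 9888, which overlaps mt-Co3 and mt-Nd3, measured 132 to 247 FPKM in 6 libraries and 7.93 to 25.8 FPKM in the other 11. The feature at 15763 to 16188 measured 35.1 to 57.7 FPKM in the 6 libraries and 9.78 to 27.0 in the 11, and the feature at 11720 to 14070 measured 28.2 to 112 and 11.9 to 23.1. A feature on chromosome 1, positions 24620805 to 24621171, followed the same split with 38.0 to 96.3 against 4.40 to 17.4 FPKM. With the set as a term, limma called 18 features between the sets. One of them, at 9203 to 9888, defined the sets, and of the other 17, 11 were higher and 6 lower in the high set.

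**Figure D5:**
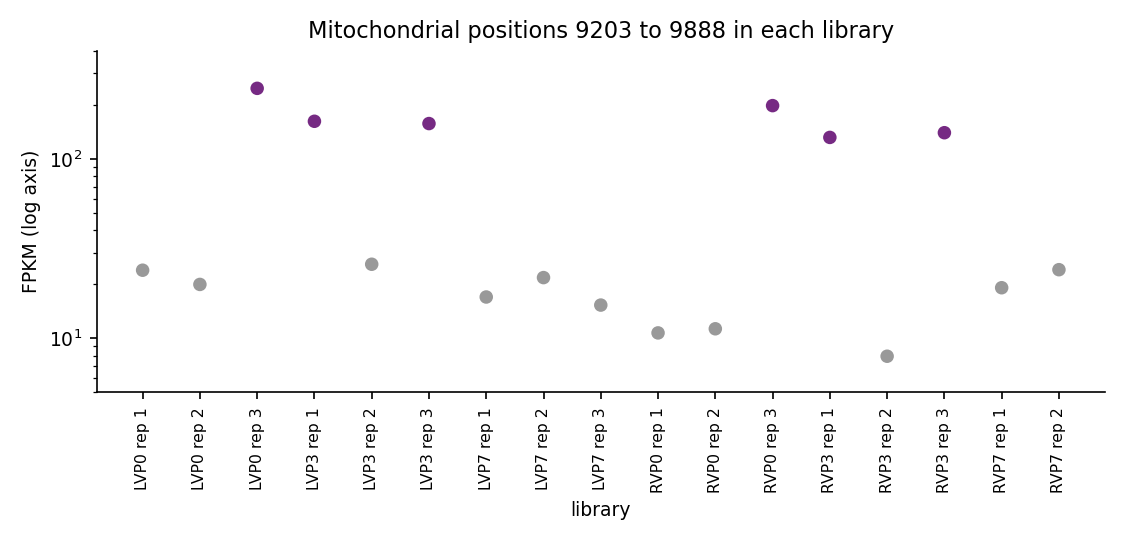
Each point is 1 library and its value in FPKM, on a log axis, at positions 9203 to 9888 of the mitochondrial chromosome. The 6 purple points, between 132 and 247 FPKM, form the high library set, and the 11 grey points, between 7.93 and 25.8 FPKM, the low set, which holds every P7 library.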

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

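The filter at 1 FPKM, the sums per position and the settings that use the library sets were chosen after seeing the data. Counts are features called by limma, with LV and RV for the left and right ventricle, and the cause of a moved count was not tested beyond the fewer libraries or more features tested that a setting brings. Without a filter, counts were 738 (LV P7 against P0), 380 (RV P7 against P0), 131 (LV P3 against P0), 53 (LV P7 against P3), 745 (any change with age), 1, 0 and 15 (RV against LV at P0, P3 and P7) and 1 (difference between ventricles). Without the variance trend, 74 and 47 features were called at P7 against P3 in LV and RV, 0 for RV against LV over the ages and 0 at P3. With only the compared groups, counts were 382 (RV P7 against P0), 172 (RV P3 against P0), 77 and 40 (P7 against P3, LV and RV) and 0 (RV against LV at P7). Median scaling gave 2 at P3 between ventricles. A pseudocount of 0.01 gave 2 at P3 and a pseudocount of 1 gave 2 at P7. In the low library set alone, counts were 636 and 370 (P7 against P0, LV and RV), 28 and 72 (P3 against P0), 4 and 2 (P7 against P3), 591 (any change with age) and 0 between ventricles over the ages, at P3 and at P7. In the high set they were 48 and 47 (P3 against P0), 2 between ventricles over the ages and 3 at P3. The high set holds no P7 library, so over the ages means P0 and P3 only there. With the set as a term, 51 and 39 were called at P7 against P3. Sums per position gave 2 between ventricles over the ages, and the filter at 1 FPKM gave 0 at P7. Leaving out each library in turn gave 666 to 1348 and 180 to 676 (P7 against P0, LV and RV), 114 to 225 and 191 to 284 (P3 against P0), 18 to 201 and 12 to 88 (P7 against P3), 0 to 3 (RV against LV over the ages), 0 to 2, 0 to 3 and 0 to 1 (P0, P3 and P7), 0 (difference between ventricles) and 916 to 1336 (any change with age). For ventricle comparisons, the replicate block paired LV and RV libraries of the same age and number. This leaves LV P7 replicate 3 without a partner. It gave 5 calls for RV against LV over the ages, 11 at P3, 2 at P7 and 1 for the difference between ventricles. Both calls at P7 were higher in RV and so without the chromosome 16 feature (limma adjusted p = 0.298). For age contrasts, the block was instead the replicate number alone, shared by all ages and both ventricles. That fit called 1213 and 529 features at P7 against P0 in LV and RV. The labels do not say that numbers pair ventricles, and deviations of same-numbered libraries correlated by 0.0451 to 0.172, not all above 0.1, though each of the 3, 3 and 2 RV libraries at P0, P3 and P7 correlated best with the LV library of its number, a hint from the data and not the design. Named features, the 12S and 16S features chosen later included, never changed sign under these alternatives, and their calls were lost in 6 cases for LV P7 against P0 and 14 for RV against 618 and 608 kept. For P3 against P0 they were lost in 16 and 9 cases against 266 and 272 kept, and for P7 against P3 in 17 and 31 cases against 254 and 236 kept. A change of sign was unlikely from the start, because most were named for large changes without overlap of the groups. Depth limits features below 1 FPKM, and planned gene lists, their alternatives and coding neighbours were not run for want of an annotation of the same build.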

Other observations

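Of the tests in this part, those of neighbouring loci, chromosomes and feature origin, of mitochondrial rRNA, depth and the library set on the left ventricle split, and of depth, age and replicate numbers on the library sets, were chosen after the results were seen. Overlapping features were merged into 8795 loci, each represented by its most abundant feature, and the loci were counted in windows of 1 Mb with at least 3 tested loci. In the left ventricle at P7 against P0, 4 of 6 loci rose in the window that starts at 23 Mb on chromosome 19 (hypergeometric test over 1222 windows, adjusted p = 0.00590), and 3 of 4 rose in the window at 114 Mb on chromosome 5 (adjusted p = 0.0336). The latter also held 3 rising loci of 4 in the right ventricle (adjusted p = 0.0269). On chromosome 5, the locus at 114056787 to 114060337 rose by 1.88 ± 0.20 and the locus at 114983964 to 114989387 by 2.70 ± 0.34 on the log2 scale in the left ventricle (SE; limma adjusted p = 5.46e-06 and 3.06e-05). In the window at 46 Mb on chromosome 8, 5 of 5 loci fell in the left ventricle (adjusted p = 0.00680), the locus at 46864582 to 46867670 by the largest log2 change, -2.85 ± 0.35 (SE; limma adjusted p = 2.21e-05). After median scaling 4 of 6 loci were still called higher on chromosome 19 and 3 of 4 on chromosome 5 in both ventricles, but more loci were called higher elsewhere, and the adjusted p values were 0.0599, 0.192 (LV) and 0.122 (RV). On chromosome 8, 3 of 5 loci were then called lower (adjusted p = 0.449). The window at 55 Mb on chromosome 14, with 12 loci, did not pass this test at P7 against P0 in either ventricle. Neighbouring loci may be parts of 1 transcript.

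Features with an assembler's ID rose more often than NONCODE features. In the left ventricle 100 of 1672 assembled features were higher at P7 and 188 of 9407 NONCODE features (5.98% and 2.0%), and in the right ventricle 91 and 112 (5.44% and 1.19%). Assembled features had the higher median level, 0.409 against 0.152 FPKM. Within 10 classes of mean level the odds ratio for rising was 2.07 in the left and 3.19 in the right ventricle (exact conditional test, p = 8.47e-08 and 5.76e-14). For falling in the left ventricle it was 0.959 (exact p = 0.659) and in the right 1.29 (exact p = 0.0362). These tests count features as independent, though features that overlap can share reads, so their p values may be too small. The calls behind them are those on the values as deposited, without median scaling. On the X chromosome, 20 of 248 loci fell in the right ventricle (8.06%, against 3.62% elsewhere; Fisher's exact test over 20 chromosomes, adjusted p = 0.0211), and 36 of 248 in the left (14.5% against 8.75%, adjusted p = 0.0621, and 0.0480 after median scaling). The right value after median scaling is not given here. The test was run for several comparisons, directions and scalings, and each adjustment covers the chromosomes of a single one. It also counts loci as independent.

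More features were lower than higher at P7 in the left ventricle, and this direction turned with median scaling. The features at mitochondrial 12S and 16S rRNA, taken over their whole spans, held 4.04% of fragments at P0 and 5.88% at P7, which lowers all other features by a log2 change of only -0.028, far from the median of -0.32. The depth of P7 libraries was 0.970 times that of P0 libraries, and among the 11 libraries of the low set 71.2% of calls were still lower, so neither depth nor the library set accounts for the split. A single scaling factor per library in the authors' normalization is consistent with the even shift over levels, with medians of -0.34, -0.37 and -0.32 in 3 equal classes of features of at least 1 FPKM, from lowest to highest level (highest minus lowest 0.022 ± 0.054, bootstrap SE). A loss of noncoding RNA relative to other RNA with age would give the same even shift and stays open, as untested.

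The 6 libraries of the high set held several times more signal at mitochondrial positions. Their depth was 1.06 times that of the other libraries of P0 and P3, all 4 groups of P0 and P3 had libraries in both sets, and the median log2 difference over all features was 0.15, against 3.59 at positions 9203 to 9888. Depth, the labelled age or a change of scale therefore do not account for the sets. Maturity within a labelled day was not tested and stays open. On the first component, P0 libraries lay at -45.32 to -25.43 and P7 libraries at 24.23 to 44.7. The low-set P3 libraries lay at 20.01 (LV) and 18.4 (RV), and the high-set ones at -13.92 and 1.02 (LV) and -7.1 and -1.18 (RV). At P0 the high-set library lay lowest in LV and between the low-set ones in RV. All 3 replicate numbers of the high set were shared by the left and the right ventricle (3 at P0, 1 and 3 at P3), which is consistent with processing in a shared batch, and this was a hint from values seen before. Shared animals or litters would give the same numbers, and no biological explanation other than the labelled age was tested.

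A comparison of 3 with 3 libraries has 10 splits, the real one included, too few for a share under 0.05. The real split was 1 of 10 with as many calls for LV P7 against P0 (1245, highest other 1), LV P3 against P0 (209, highest other 1), LV P7 against P3 (148, highest other 0) and RV P3 against P0 (273, highest other 0). For RV against LV at P0 the real count was 0, which all 10 of 10 splits reach by construction, so that comparison tests nothing (highest other 2). At P3, 2 of 10 gave at least 1 (highest other 1). For any change with age, 1 of 100 splits of the libraries within each ventricle, the real one, gave 1173 calls, and the highest other gave 65, so chance is excluded at that level. For RV against LV over the ages, 7 of 100 splits within ages gave at least the 1 real call (highest other 3), so chance is not excluded for that count.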
